A study of Homo sapiens with 30 samples.

How the data were processed

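Bulk RNA-seq values of 30 libraries of the HUES8 line were used, 6 for each of the groups ESC, DE, PE, PP and sorted PP. Per the labels, all cells were wild type, RNA was isolated with a column kit, samples had RNA integrity numbers above 8, up to 1 µg of total RNA was enriched for poly-A RNA, and stranded libraries were made. Per the submitters' processing notes, STAR, DESeq2 (version 1.22.1) and deepTools were used with the hg38 assembly, without a statement of which tool made which values. Sequencing depth, the strand setting of counting, gene annotation release, culture identity of the libraries and the manner of sorting are not given in the sources used here.

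Both deposited tables covered the same 58051 genes and 30 libraries and no other samples. By their names, the first held FPKM and the second variance-stabilised counts, and the steps that made them are not described further in the sources used here. Comparison of the tables showed that the deposited FPKM values had been scaled by the authors with the same library factors as the second table, since the ratio of FPKM to normalised counts was constant per gene with a coefficient of variation of at most 1.65e-07. The deposited variance-stabilised values had been put on a log2 scale by the authors from normalised counts, as shown by the inversion described below. FPKM therefore did not sum to a common total, and sums ran from 336512 to 438558 per library. The header line of the FPKM table was shifted by 1 column, and this was corrected. Of its gene names, 27 had been turned into dates, and symbols were taken from the second table for these. Genes were kept apart by Ensembl ID, because 1747 entries shared a symbol with another. Of 526 gene list entries, 4 were matched through a reference table because the tables carried older symbols, and 0 stayed unmatched.

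The variance-stabilising function was inverted in closed form, and the values obtained were whole multiples of a constant per library. All values lay within 0.01 of a whole number, so the reads behind each value were recovered. This gave 8.64 to 22.6 M reads per library. Median-of-ratios factors computed from FPKM of the kept genes lay between 0.998 and 1.01. No table held raw counts, so tests for raw counts were not run, and the recovered reads served for depth and for an alternative only.

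Genes with an FPKM of at least 1 in at least 6 of the 30 libraries were tested, 17437 in all. Values were analysed as log2(FPKM + 1) with limma (version 3.58.1 in R 4.3.3), fitting 1 mean per group to all 30 libraries with 25 residual degrees of freedom and a trended prior variance. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05 with a change of at least 1 on the log2 scale. Comparisons were DE against ESC, PE against DE, PP against PE and sorted PP against PP. Stage-variable genes were those with an adjusted p below 0.05 in limma's moderated F test over the 5 groups and a range of group means of at least 1. No p-value in the text came from another test unless named there.

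Gene lists were tested with camera in limma at a correlation between genes preset at 0.01, adjusting over 29 lists and 4 comparisons, 116 tests in all. An alternative estimated the correlation of each list from the data. The 31 lists covered pluripotency, primitive streak, definitive endoderm, gut tube, pancreatic progenitor regulators, endocrine regulators, islet hormones, acinar, ductal and monogenic diabetes genes. They also covered markers of liver, intestine, stomach, mesenchyme, endothelium, neural ectoderm and blood, and cell cycle, Nodal, Wnt, Notch, retinoic acid, Hedgehog, HOX, epithelial, EMT, glycolysis, respiratory chain, mitochondrial mRNA, immediate early and ribosomal protein genes. The blood and the stomach and anterior foregut lists had fewer than 5 measured genes and were not tested. Lists shared members, so their results are not independent.

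Groups, comparisons, lists, thresholds and the rule for naming genes were chosen before the data were examined. In each comparison the rule named ONECUT1, ONECUT2, ONECUT3, PDX1 and NKX6-1, the 8 largest rises and 8 largest falls whose groups did not overlap, and up to 4 called members of each list described. Some genes that the rule names are not reported here. The rule left out XIST, Y-linked genes and names that are only clone identifiers. Where fewer than 2 members of a list were called, those of smallest p were given as values.

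Alternatives changed the pseudocount, filter, table, scaling, groups in the fit, replicate block, variance prior, minimum change and list correlation, and left out each library in turn. Alternatives added after the values had been seen averaged or linked libraries of adjacent number, left out pairs of numbers, used voom on recovered reads, scaled to total reads, or kept protein-coding genes only. Libraries of equal number correlated above 0.1 between neighbouring stages in only 7 of 24 cases, so numbers were not used as pairs. Chi-square per degree of freedom between libraries of a group ran from 1.81 to 5.73 for the 15 pairs of adjacent number and from 4.08 to 57.1 for other pairs, so no library was a copy of another, while adjacent numbers lay closest to counting noise.

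The procedure was run on simulated values with known changes. Of genes changed 4-fold it recovered 99, 99, 100.0 and 100.0 of 100 in the 4 comparisons, and of genes changed 2-fold 9, 8, 15 and 13 of 50. A 2-fold change in FPKM lies under the minimum of 1 on the log2(FPKM + 1) scale. All 50 genes changed 8-fold were recovered, and 1, 6, 3 and 1 of 17237 unchanged genes were called. The F test recovered 199 of 200 genes with 2 false calls. Of 100 unchanged lists per comparison, 2, 1, 0 and 1 had p below 0.05, and reads were recovered for 100% of 5000 simulated genes. Genes and libraries were drawn independently in these simulations, and the unchanged lists were random. The simulated error rates therefore do not cover lists whose genes move together, or libraries of adjacent number that resemble each other. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for preparation and figures.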

Results

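RNA was sequenced from HUES8, a human embryonic stem cell line, at successive stages of differentiation towards the pancreas in culture. The 30 libraries formed 5 groups of 6, namely undifferentiated embryonic stem cells (ESC), definitive endoderm (DE), pancreatic endoderm (PE), pancreatic progenitors (PP), and progenitors positive for both PDX1 and NKX6.1 (sorted PP). All libraries came from wild-type cells, and the stated aim was to follow gene expression, with attention to the transcription factor ONECUT1, along this path. Reads assigned to genes ran from 8.64 to 22.6 M per library. Means ± SD (n = 6) in M reads were 15.5 ± 5.35 in ESC, 13.1 ± 4.62 in DE, 13.7 ± 5.26 in PE, 16.9 ± 3.91 in PP and 13.4 ± 4.70 in sorted PP. The number of genes at an FPKM of 1 or more lay between 14559 and 15392 in every library. Mitochondrially encoded genes took 10.4 ± 2.98% of summed FPKM in ESC, 12.4 ± 3.51% in DE, 10.8 ± 0.725% in PE, 13.4 ± 1.48% in PP and 16.7 ± 0.871% in sorted PP.

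Values below are mean FPKM ± SD over the 6 libraries of a group (n = 6). Changes are differences of mean log2(FPKM + 1) ± standard error, a scale that understates the change of genes expressed at a low level. Standard errors and p-values of a gene rest on its spread pooled over all 5 groups, not on the compared groups alone. A gene is said to have risen or fallen where its adjusted p in limma was below 0.05 and its change was at least 1 on that scale. Counts and tests of gene lists cover only members with an FPKM of at least 1 in at least 6 libraries. A member high in a single group could pass through that group alone, which favours changes into and out of it. The labels number the libraries of each group from 1 to 6 without saying that these are separate cultures, so the p-values measure only the spread between these libraries. Libraries of a group with adjacent numbers, such as 1 and 2, tended to deviate from the group mean together, since 13 of 15 such pairs correlated more highly than any other pair of their group. The strand setting used in counting is not given in the sources used here, so values of genes that overlap another gene on the opposite strand are uncertain.

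ONECUT1 (ENSG00000169856; hg38 chromosome 15, 52756989 to 52791078), a homeodomain transcription factor of liver and pancreas development, was nearly silent in DE and highest in PE. Its FPKM was 2.86 ± 1.98 in ESC, 0.0924 ± 0.0969 in DE, 27.9 ± 4.44 in PE, 22.0 ± 1.17 in PP and 7.56 ± 0.823 in sorted PP. ONECUT2 (ENSG00000119547; chromosome 18, 57435685 to 57491297) measured 0.452 ± 0.154, 2.42 ± 1.76, 18.0 ± 9.03, 16.0 ± 3.90 and 6.60 ± 0.800 in the same order. ONECUT3 (ENSG00000205922; chromosome 19, 1752373 to 1780988) came later, at 0.323 ± 0.0844 in PE, 7.05 ± 0.476 in PP and 7.34 ± 0.766 in sorted PP. PDX1 (ENSG00000139515; chromosome 13, 27920020 to 27926231), required for formation of the pancreas, was 0 in all 6 ESC libraries and measured 34.5 ± 6.77 in PE, 63.0 ± 7.48 in PP and 113 ± 38.3 in sorted PP. NKX6-1 (ENSG00000163623; chromosome 4, 84491987 to 84498450), a regulator of progenitors that give rise to beta cells, was 0.00501 ± 0.00779 in PE, 24.9 ± 7.13 in PP and 80.1 ± 15.7 in sorted PP. The pluripotency factor POU5F1 went from 297 ± 33.2 in ESC to 24.8 ± 15.4 in DE and 0.218 ± 0.0635 in PE. The endoderm factor SOX17 went from 0.0102 ± 0.0160 in ESC to 120.4 ± 18.0 in DE and 1.53 ± 0.492 in PE.

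**Figure D1:**
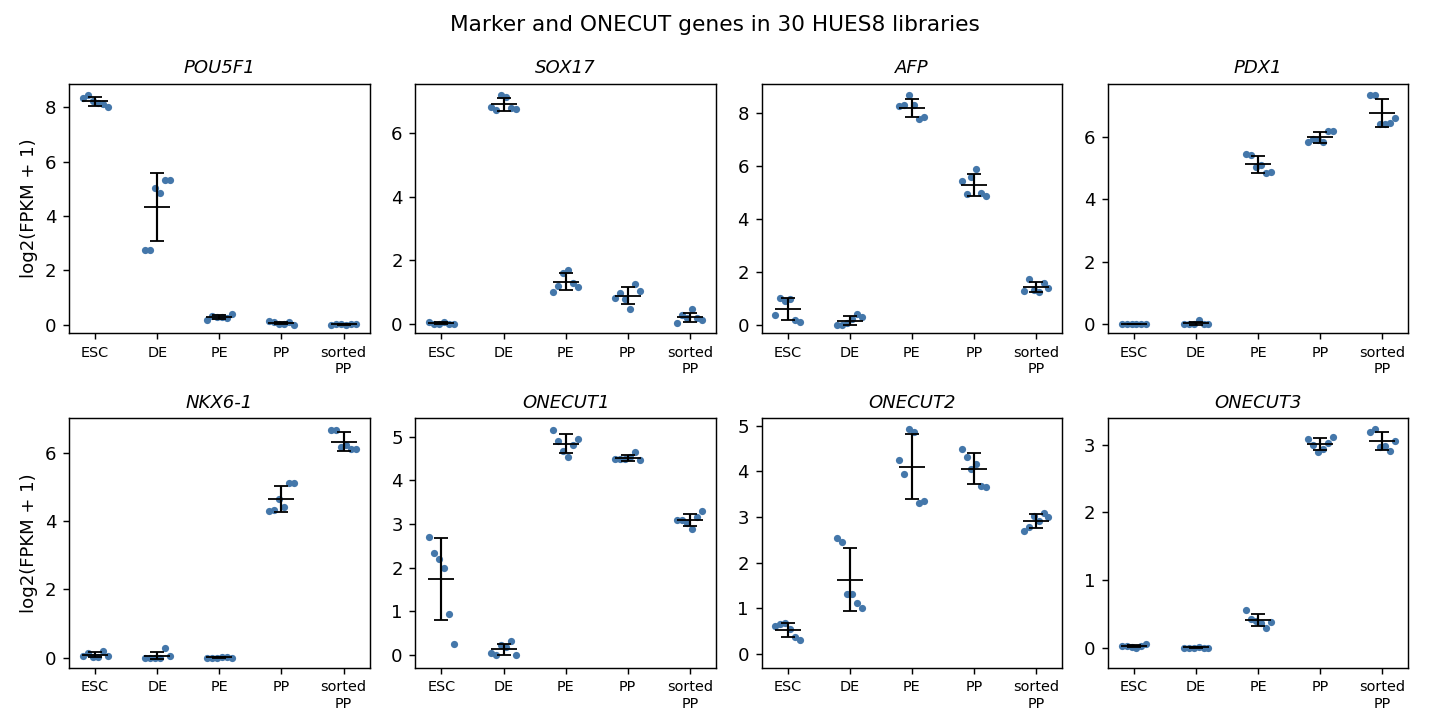
Expression of 8 genes in the 5 groups (x axis) as log2(FPKM + 1) (y axis); each dot is 1 library and the bars give the mean ± SD of 6 libraries. POU5F1 was highest in ESC, SOX17 in DE, and AFP and ONECUT1 in PE, while NKX6-1 averaged 24.9 FPKM in PP and 80.1 FPKM in sorted PP.

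Across the 5 groups, 8381 of 17437 genes tested varied between stages by limma's moderated F test with a range of at least 1. Their highest mean lay in ESC for 2859 genes, in DE for 1824, in PE for 1316, in PP for 921 and in sorted PP for 1461. The stage of the highest mean was picked from the data and was not itself tested.

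Comparing DE with ESC asked which transcripts distinguish definitive endoderm from the stem cells it was made from. DE libraries held high levels of endoderm and Nodal pathway transcripts that were low in ESC. CER1 (ENSG00000147869; chromosome 9, 14719724 to 14722717), a secreted antagonist of Nodal, BMP and Wnt signals, rose from 3.39 ± 0.836 to 8119 ± 1827 (change 10.85 ± 0.31, adjusted p = 4.1e-23). All 15 measured genes of the definitive endoderm list rose, among them SOX17, from 0.0102 ± 0.0160 to 120.4 ± 18.0, and the chemokine receptor CXCR4, from 1.04 ± 0.479 to 361 ± 111. All 9 measured genes of the primitive streak and mesendoderm list rose as well, including the T-box factor EOMES, from 0.0754 ± 0.0326 to 155 ± 7.53, the homeobox factor GSC, from 0.0750 ± 0.0697 to 85.9 ± 8.33, and FGF17, from 0.565 ± 0.133 to 1063 ± 64.0. By camera, both lists stood above other genes, with adjusted p = 7.1e-14 and 6.0e-10 at the preset correlation of 0.01 and 0.00012 for each with an estimated correlation. Members of these lists that stayed low in all groups were left out by the filter. A member near 0 in ESC could pass through DE alone, so these counts and p-values partly follow from the filter. The endoderm factors FOXA2, GATA6 and GATA4 reached 51.3 ± 3.53, 95.6 ± 14.7 and 68.6 ± 18.6 from levels below 0.1 in ESC, and all of them rose.

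Pluripotency genes went the other way in DE, with 12 of 20 falling and none rising (adjusted p = 4.4e-05; adjusted p = 0.055 with an estimated correlation). SOX2 fell by 6.08 ± 0.37, from 125 ± 24.7 to 0.901 ± 0.554, and the DNA methyltransferase DNMT3B fell from 592 ± 245 to 57.9 ± 8.85. POU5F1 fell to a mean of 24.8, with DE libraries 1 and 2 lowest at 5.71 and 5.78. The largest fall was in ESRG (ENSG00000265992; chromosome 3, 54632122 to 54639857), a non-coding transcript known from pluripotent cells, which fell by 6.54 ± 0.08, from 691 ± 41.0 to 6.53 ± 1.45. LECT1, the long non-coding RNAs LINC00678 and MIAT, the secreted phosphoprotein SPP1, the neuronal pentraxin NPTX1 and the metallothionein MT1X fell as well. ONECUT1 fell by 1.61 ± 0.24 (adjusted p = 6.5e-07), while its ESC values ran from 0.182 in library 6 to 5.45 in library 1. ONECUT2 rose by 1.10 ± 0.26 (adjusted p = 4.0e-04), a change of 0.72 without libraries 1 and 2 of each group, 0.91 without DE library 1 and 0.93 without DE library 2, all below the minimum of 1.

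Nodal and Wnt target lists were higher in DE. Of 12 Nodal and Activin targets, 8 rose and none fell (adjusted p = 1.3e-05; adjusted p = 0.051 with an estimated correlation). Beside CER1 these included the feedback inhibitors LEFTY2, from 2.04 ± 0.709 to 2052 ± 389, and LEFTY1, from 1.57 ± 1.47 to 417 ± 82.3. LEFTY1 and LEFTY2 are close paralogs, so the split of reads between them is uncertain. Of 9 Wnt targets, 5 rose, including LGR5, from 0.0326 ± 0.0187 to 24.2 ± 7.67, and the antagonist DKK1, from 0.0770 ± 0.0574 to 21.9 ± 15.6 (adjusted p = 0.016; adjusted p = 0.04993 with an estimated correlation). The remaining genes with the largest rises were CYP26A1, which degrades retinoic acid, from 3.39 ± 0.959 to 727 ± 147, and the gastrin receptor CCKBR, from 0.591 ± 0.236 to 245 ± 18.2. The gut tube and posterior foregut list (7 rose, 2 fell; adjusted p = 0.027; adjusted p = 0.097 with an estimated correlation) was higher. So was the monogenic diabetes list (8 rose, 3 fell; adjusted p = 0.027; adjusted p = 0.052 with an estimated correlation), and both lists contained GATA6 and GATA4, which rose. In the list of regulators of epithelial-mesenchymal transition (EMT), 4 of 8 genes rose and 1 fell, among them N-cadherin CDH2, from 12.4 ± 3.14 to 319 ± 40.5, and fibronectin FN1, from 41.0 ± 5.94 to 273 ± 57.4 (adjusted p = 0.045; adjusted p = 0.29 with an estimated correlation). That call was also lost with the replicate number as a block (adjusted p = 0.052) and with libraries of adjacent number averaged (adjusted p = 0.051).

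The cell cycle and glycolysis lists were lower in DE, while the nuclear respiratory chain (adjusted p = 0.12) and mitochondrially encoded mRNA (adjusted p = 0.28) lists were not called. Of 20 cell cycle genes, 16 fell and none rose, including the checkpoint kinase BUB1, from 84.3 ± 14.8 to 20.7 ± 3.36, and TOP2A, from 100.5 ± 31.2 to 29.2 ± 3.90 (adjusted p = 2.7e-06; adjusted p = 0.19 with an estimated correlation). Of 19 glycolysis genes, 12 fell, with hexokinase HK1 from 113 ± 23.4 to 18.2 ± 1.10, and 1 rose (adjusted p = 8.0e-04; adjusted p = 0.46 with an estimated correlation). As measures of RNA quality and handling, none of 23 ribosomal protein genes passed the minimum change although the list was lower at a median of -0.63 (adjusted p = 3.0e-06; adjusted p = 0.42 with an estimated correlation). In the immediate early and heat shock list, 6 of 17 genes rose, led by IER3 from 2.48 ± 0.742 to 98.4 ± 22.5 (adjusted p = 0.0075; adjusted p = 0.29 with an estimated correlation).

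In total 3629 of 17437 genes changed between DE and ESC, 1746 higher and 1883 lower in DE, of which 2871 were protein-coding. For 8389 of all genes tested, 3488 of the changed ones among them, the libraries of both groups did not overlap, which chance gives to 0.216% of genes if all 12 libraries can be exchanged, and to 10% if only the averages of adjacent numbers can. Of 29 gene lists tested, 12 were called, 8 higher and 4 lower, and the definitive endoderm, primitive streak and Wnt target lists held with an estimated correlation. In each list of every comparison, the counts of genes that rose or fell were identical when p-values were adjusted over the list alone.

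Comparing PE with DE asked what accompanies the step from endoderm to pancreatic endoderm. The gut tube, pancreatic progenitor and liver lists were higher in PE, while most Nodal target and streak genes fell. PDX1 rose by 5.11 ± 0.14 (adjusted p = 8.7e-24), ONECUT1 by 4.72 ± 0.24 (adjusted p = 7.7e-17) and ONECUT2 by 2.47 ± 0.26 (adjusted p = 1.2e-09). Of 20 pancreatic progenitor regulators, 11 rose and 1 fell, with RFX6 reaching 38.0 ± 10.3 from 0.0194 ± 0.0299 and the Notch effector HES1 reaching 52.9 ± 4.33 from 2.68 ± 2.17 (adjusted p = 3.3e-05; adjusted p = 0.052 with an estimated correlation). NKX6-1 stayed near 0 in PE, at 0.00501 ± 0.00779.

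Of 14 gut tube and posterior foregut genes, 10 rose and 1 fell, led by the cadherin CDH6 and the homeobox factor MEIS1, from 0.254 ± 0.0544 to 27.3 ± 2.36 (adjusted p = 2.9e-06). The ductal and trunk list followed with 9 of 14 genes rising and 1 falling, including SOX9, from 0.300 ± 0.193 to 15.7 ± 4.30 (adjusted p = 4.6e-05). In the monogenic diabetes list 7 of 18 genes rose and 2 fell, including HNF4A, from 1.41 ± 0.507 to 17.4 ± 0.807 (adjusted p = 0.0071). All 8 HOX genes that passed the low-value filter rose, with HOXA3 from 0.00817 ± 0.0133 to 14.4 ± 1.42 (adjusted p of the list = 7.6e-08). Most members of the HOX list were too low to be tested, so this count does not describe the whole list. A gene near 0 in DE could pass only through other groups, which favours a rise. Retinoic acid targets rose in 8 of 12 cases and fell in 1, with DHRS3 from 1.71 ± 0.564 to 70.9 ± 8.64 and CYP26B1 from 0.0993 ± 0.0627 to 71.1 ± 52.7 (adjusted p = 4.9e-06).

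Liver and intestine markers were higher as lists beside the pancreatic genes. Of the other tissue lists, none was called, with 3 genes rising and 2 falling for mesenchyme (adjusted p = 0.68), 0 and 3 for endothelium (adjusted p = 0.12) and 1 and 4 for neural ectoderm (adjusted p = 0.051). Of 10 liver genes, 9 rose (adjusted p = 9.1e-09). They included AFP (ENSG00000081051; chromosome 4, 73431138 to 73456174), the fetal serum protein, from 0.131 ± 0.136 to 296 ± 68.7. The fibrinogen chain FGB rose from 0.0299 ± 0.0541 to 123 ± 49.1 and the thyroxine carrier TTR from 0.0102 ± 0.0250 to 111 ± 21.6. The plasma protein AMBP also rose, from 0.0281 ± 0.0313 to 80.7 ± 14.5. In the intestine list 3 of 7 genes rose, among them CDX2, from 0.0138 ± 0.0155 to 13.2 ± 4.56 (adjusted p = 0.029; adjusted p = 0.23 with an estimated correlation). The stem cell receptor LGR5, also on that list, fell from 24.2 ± 7.67 to 0.0415 ± 0.0265. SOX2, on the pluripotency and the stomach and anterior foregut lists, rose from 0.901 ± 0.554 to 41.1 ± 17.2. The largest rises belonged to the neighbouring imprinted genes H19 (ENSG00000130600; chromosome 11, 1995163 to 2001470), from 1.30 ± 1.64 to 3138 ± 931, and the growth factor IGF2, from 1.10 ± 0.515 to 1201 ± 168, the latter overlapping IGF2-AS on the opposite strand.

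Most genes of the streak, Nodal target and definitive endoderm lists fell in PE. CER1 fell by 9.31 ± 0.31, from 8119 ± 1827 to 11.9 ± 3.01, LEFTY2 fell by 8.80 ± 0.30 and FGF17 fell by 8.24 ± 0.08. Of 9 streak and mesendoderm genes 8 fell and none rose (adjusted p = 5.9e-10), of 12 Nodal and Activin targets 9 fell and none rose (adjusted p = 2.8e-07), and of 15 definitive endoderm genes 11 fell and none rose (adjusted p = 5.2e-06). SOX17 fell to 1.53 ± 0.492 and CXCR4 to 5.17 ± 0.729. In the pluripotency list 14 of 20 genes fell, led by the Nodal co-receptor TDGF1, from 359 ± 74.6 to 1.59 ± 0.508, and only SOX2 rose (adjusted p = 2.4e-06). The embryonic stem cell microRNA gene MIR302D, which lies opposite LARP7, and the hormone gene STC1 fell from 138 ± 13.2 to 0.122 ± 0.298 and from 222 ± 86.6 to 0.688 ± 0.167. Wnt targets fell in 5 of 9 cases and rose in 1 (adjusted p = 0.044; adjusted p = 0.097 with an estimated correlation), with DKK1 from 21.9 ± 15.6 to 0.628 ± 0.195. The Wnt list call was lost with the replicate number as a block (adjusted p = 0.052) and with libraries of adjacent number averaged (adjusted p = 0.051). Glycolysis genes fell in 7 of 19 cases, with the glucose transporter SLC2A3 from 1072 ± 231 to 82.8 ± 10.8 (adjusted p = 5.4e-04; adjusted p = 0.44 with an estimated correlation). Ribosomal protein genes were again lower as a list, at a median of -0.46, with none of 23 passing the minimum change (adjusted p = 1.6e-04; adjusted p = 0.54 with an estimated correlation).

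Epithelial junction and keratin genes rose in 6 of 15 cases, including E-cadherin CDH1, from 18.3 ± 5.18 to 105 ± 19.0, and the epithelial regulator GRHL2, from 0.666 ± 0.191 to 9.63 ± 1.40 (adjusted p = 0.036; adjusted p = 0.44 with an estimated correlation). In all, 2844 genes changed between PE and DE, 1459 higher and 1385 lower in PE, and 2337 of them were protein-coding. The groups did not overlap for 8059 of the 17437 genes tested, against 0.216% by chance with all libraries exchangeable and 10% with averages of adjacent numbers. Of 29 lists, 17 were called, 10 higher and 7 lower, and 10 of these held with an estimated correlation, namely gut tube, ductal, monogenic diabetes, liver, HOX, retinoic acid, primitive streak, definitive endoderm, Nodal and pluripotency. Median, mean and test differed in sign for the mesenchyme, islet hormone and EMT lists, none of which was called.

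**Figure D2:**
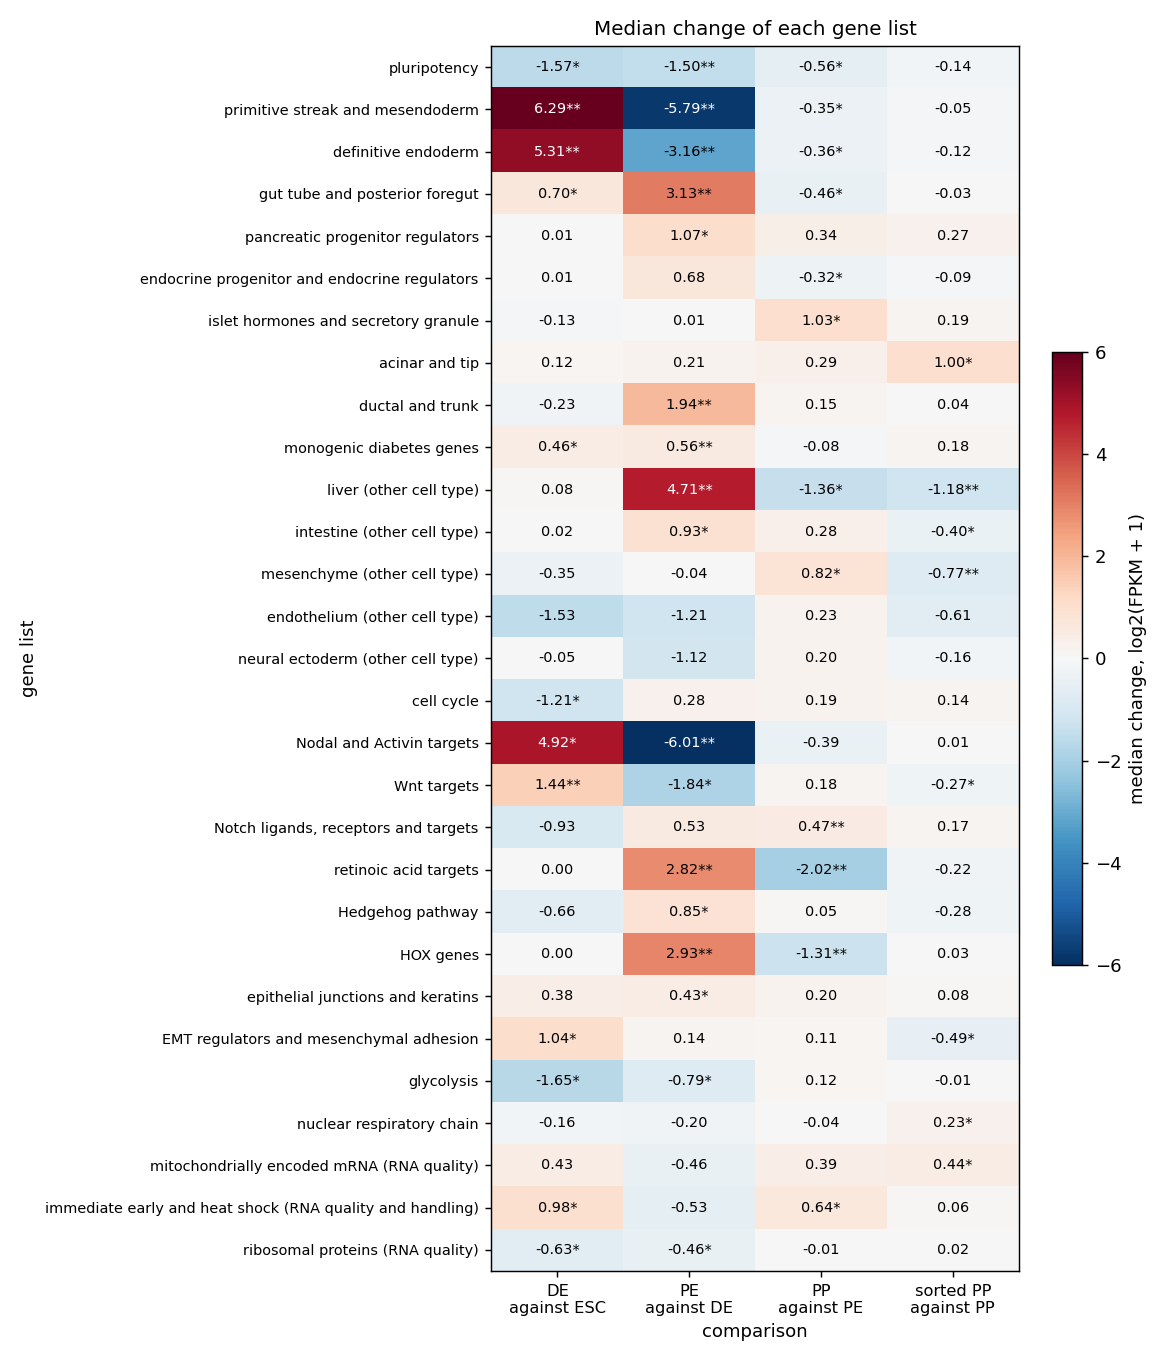
Median change on the log2(FPKM + 1) scale of each of 29 gene lists (rows) in the 4 comparisons (columns), with colour running from blue (lower) to red (higher); 1 asterisk marks a list called at the preset correlation and a pair of asterisks a list called with an estimated correlation as well. The primitive streak and mesendoderm list had medians of 6.29 in DE against ESC and -5.79 in PE against DE.

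Comparing PP with PE asked what changes as pancreatic endoderm becomes a progenitor population. NKX6-1 appeared at this step and rose by 4.64 ± 0.12 (adjusted p = 5.7e-23), from 0.00501 ± 0.00779 to 24.9 ± 7.13, and ONECUT3 rose by 2.61 ± 0.06 (adjusted p = 2.4e-24), from 0.323 ± 0.0844 to 7.05 ± 0.476. ONECUT1 was 27.9 ± 4.44 in PE and 22.0 ± 1.17 in PP (change -0.32 ± 0.24, adjusted p = 0.30). Its standard error and p-value pool the spread of all 5 groups, and its ESC libraries ran from 0.182 to 5.45. That p-value therefore does not measure the spread of PE and PP alone. ONECUT2 was 18.0 ± 9.03 in PE and 16.0 ± 3.90 in PP (change -0.04 ± 0.26, adjusted p = 0.92). The direction of that ONECUT2 difference turned with single libraries, to 0.12 without PE library 3, 0.11 without PE library 4, 0.03 without PP library 5 and 0.04 without PP library 6. PDX1 was 34.5 ± 6.77 in PE and 63.0 ± 7.48 in PP, a change of 0.87 ± 0.14 (adjusted p = 5.2e-06) that stayed under the minimum of 1 and reached 1.07 without libraries 1 and 2 of each group. Of 20 pancreatic progenitor regulators, 8 rose and 4 fell, with DLK1 going from 6.57 ± 0.864 to 158 ± 53.9 and RFX6 from 38.0 ± 10.3 to 3.19 ± 1.60. The list as a whole was not called (adjusted p = 0.080).

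The retinoic acid target and HOX lists, which had been higher in PE than in DE, were lower in PP. CYP26A1 (ENSG00000095596; chromosome 10, 93073475 to 93077890) fell by 6.41 ± 0.16, from 125 ± 36.1 to 0.443 ± 0.213. It had not risen in PE, since its level in DE was 727 ± 147. CYP26B1 fell by 4.97 ± 0.24, and the receptor gene RARB fell from 25.2 ± 1.86 to 1.18 ± 0.715. In the retinoic acid list 9 of 12 genes fell and none rose (adjusted p = 8.1e-11), and in the HOX list 6 of 8 fell and none rose (adjusted p = 5.0e-10). Of 15 Notch pathway genes 6 rose and 1 fell, with the ligand JAG1 from 4.67 ± 0.932 to 115 ± 9.98 and the targets HEY1 from 0.311 ± 0.127 to 11.2 ± 4.83 and NRARP from 2.90 ± 0.474 to 15.7 ± 2.18 (adjusted p = 7.4e-04). CCND1 (ENSG00000110092; chromosome 11, 69641087 to 69654474), a cyclin that drives entry into S phase and overlaps ORAOV1 on the opposite strand, had the largest rise, from 6.01 ± 0.959 to 243 ± 20.3. Other large rises were those of the cobalamin carrier TCN1, from 9.48 ± 2.46 to 373 ± 159.6, and the membrane protein TTYH1, from 4.67 ± 0.959 to 182 ± 22.6. IGFBP7, which overlaps POLR2B on the opposite strand, rose from 6.61 ± 2.71 to 158 ± 35.3 and the chemokine CXCL1 from 1.18 ± 0.626 to 43.0 ± 6.94.

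Hormone and lineage markers were uneven in PP. In the islet hormone and secretory granule list 6 of 12 genes rose and 1 fell (adjusted p = 0.014; adjusted p = 0.31 with an estimated correlation). Among the genes that rose were glucagon GCG, 0 in all 6 PE libraries and 14.2 ± 16.8 in PP, somatostatin SST, from 0.0562 ± 0.0908 to 7.98 ± 8.43, and insulin INS, from 0.0185 ± 0.0453 to 7.94 ± 8.80. INS was 0 in PP libraries 1 and 2, 5.74 and 4.47 in libraries 3 and 4, and 21.2 and 16.3 in libraries 5 and 6. The list of endocrine regulators was lower, with RFX6 and LMX1B falling and none of 9 rising (adjusted p = 0.043; adjusted p = 0.15 with an estimated correlation), a call also lost with libraries of adjacent number averaged (adjusted p = 0.051). In the ductal and trunk list, not called at adjusted p = 0.13, SPP1 rose from 1.78 ± 0.732 to 70.3 ± 15.2 and the bicarbonate transporter SLC4A4 from 10.7 ± 3.58 to 82.9 ± 7.15. In the acinar and tip list, not called at adjusted p = 0.49, the carboxypeptidase CPB1 fell from 56.6 ± 30.5 to 1.58 ± 1.45.

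Liver genes fell in 6 of 10 cases and rose in 1, with AFP going from 296 ± 68.7 to 38.9 ± 11.6 and FGB from 123 ± 49.1 to 25.5 ± 9.29 (adjusted p = 7.8e-04; adjusted p = 0.052 with an estimated correlation). Mesenchyme genes rose in 4 of 9 cases and fell in 1, with the collagens COL1A2 from 5.12 ± 1.86 to 67.2 ± 13.9 and COL3A1 from 2.18 ± 0.851 to 13.3 ± 4.45 (adjusted p = 0.023; adjusted p = 0.16 with an estimated correlation). The gut tube list was lower, with 3 of 14 genes falling, OSR1 among them, and 1 rising, SOX9, from 15.7 ± 4.30 to 83.9 ± 4.19 (adjusted p = 0.041; adjusted p = 0.12 with an estimated correlation). Further falls were those of the lipid transfer protein MTTP, which overlaps TRMT10A, from 47.3 ± 5.58 to 0.580 ± 0.126, the glutathione transferase GSTA1 and the cannabinoid receptor CNR1, from 20.8 ± 1.85 to 0.593 ± 0.0979. Early lineage lists were lower in PP. The pluripotency list had 5 of 20 genes falling (adjusted p = 7.8e-04; adjusted p = 0.12 with an estimated correlation), and the primitive streak list 2 of 9 (adjusted p = 0.0084; adjusted p = 0.055 with an estimated correlation). In the definitive endoderm list 5 of 15 genes fell and 2 rose (adjusted p = 0.0094; adjusted p = 0.11 with an estimated correlation). Among definitive endoderm genes GATA4 fell from 86.5 ± 4.76 to 11.5 ± 1.08 while CER1 rose from 11.9 ± 3.01 to 76.9 ± 28.1. Immediate early and heat shock genes rose in 7 of 17 cases, with EGR1 from 4.01 ± 2.29 to 50.2 ± 9.71 (adjusted p = 4.6e-05; adjusted p = 0.11 with an estimated correlation). That list was chosen as a measure of handling, but handling was not told apart from other causes of the rise.

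Between PP and PE 1022 genes changed, 496 higher and 526 lower in PP, of which 899 were protein-coding. Of the 17437 genes tested, 5683 had groups that did not overlap, against 0.216% by chance with all libraries exchangeable and 10% with averages of adjacent numbers. Of 29 lists, 12 were called, 4 higher and 8 lower, and the retinoic acid, HOX and Notch lists held with an estimated correlation. Median, mean and test differed in sign for the acinar, Nodal, ribosomal and Hedgehog lists, none of which was called.

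Comparing sorted PP with PP asked what sets the cells positive for PDX1 and NKX6.1 apart from the whole culture. Both genes that define the gate had higher means. NKX6-1 rose by 1.67 ± 0.12 (adjusted p = 2.0e-11), from 24.9 ± 7.13 to 80.1 ± 15.7. PDX1 was 63.0 ± 7.48 in PP and 113 ± 38.3 in sorted PP, a change of 0.78 ± 0.14 under the minimum (adjusted p = 4.9e-05). ONECUT1 fell by 1.43 ± 0.24 (adjusted p = 2.9e-05), from 22.0 ± 1.17 to 7.56 ± 0.823, and every sorted library, at 6.34 to 8.81, lay below every PP library, at 21.2 to 24.3. ONECUT2 fell by 1.14 ± 0.26 (adjusted p = 9.3e-04), from 16.0 ± 3.90 to 6.60 ± 0.800, although its adjusted p was 0.0515 when libraries of adjacent number were averaged and 0.0568 without libraries 1 and 2 of each group. ONECUT3 was 7.05 ± 0.476 in PP and 7.34 ± 0.766 in sorted PP (change 0.05 ± 0.06, adjusted p = 0.58), with a change of -0.02 without libraries 1 and 2 of each group. Of 20 pancreatic progenitor regulators, PTF1A, DLK1 and NKX6-1 rose and ONECUT1 and ONECUT2 fell, and the list was not called (adjusted p = 0.081).

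Acinar and tip genes were higher in sorted PP, with 3 of 7 rising and none falling (adjusted p = 0.0023; adjusted p = 0.13 with an estimated correlation). PTF1A (ENSG00000168267; chromosome 10, 23192327 to 23194252), a factor of multipotent and acinar progenitors, rose from 0.357 ± 0.529 to 8.22 ± 7.75. Sorted libraries 1 and 2 stood apart from libraries 3 to 6, with PTF1A at 19.2 and 17.1 against 2.44 to 3.90 and DLK1 at 1462 and 1437 against 270.0 to 470.0. They also had the highest PDX1, at 162 and 163 against 84.6 to 96.9, and the lowest SPP1, at 12.5 and 10.4 against 72.7 to 84.5. CPA1 rose from 0.475 ± 0.480 to 3.56 ± 3.19, a change of 0.64 and under the minimum without libraries 1 and 2 of each group. Of 15 Notch pathway genes, HEY1, DLL1 and HEYL rose and none fell (adjusted p of the list = 0.052), with HEY1 from 11.2 ± 4.83 to 41.0 ± 2.27. The changes of DLL1 and HEYL were 0.71 and 0.80 without libraries 1 and 2 of each group. That of HEYL was also under the minimum without PP library 1 (0.96), 3 (0.99) or 4 (0.94). The same held without sorted library 1 (0.93) or 2 (0.97), without libraries 3 and 4 of each group (0.99), and on the variance-stabilised scale (0.86).

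Liver and mesenchyme markers were lower in sorted PP. Of 10 liver genes 6 fell and none rose (adjusted p = 1.3e-05), with AFP falling by 3.84 ± 0.18, from 38.9 ± 11.6 to 1.71 ± 0.371, FGB from 25.5 ± 9.29 to 3.04 ± 1.60 and TTR from 97.7 ± 11.1 to 19.6 ± 3.04. Of 9 mesenchyme genes 3 fell and none rose (adjusted p = 4.6e-05), with COL3A1 (ENSG00000168542; chromosome 2, 188974320 to 189012746) falling by 3.29 ± 0.15, from 13.3 ± 4.45 to 0.423 ± 0.231, and the smooth muscle actin ACTA2 from 7.33 ± 1.66 to 0.444 ± 0.178. The intestine list was lower, with CDH17 falling from 5.21 ± 1.63 to 0.439 ± 0.206 (1 of 7 fell; adjusted p = 0.016; adjusted p = 0.19 with an estimated correlation). The EMT list was lower, with vimentin VIM falling (1 of 8 genes; adjusted p = 0.023; adjusted p = 0.23 with an estimated correlation). The Wnt target list was lower, with DKK1 falling (1 of 9 genes; adjusted p = 0.027; adjusted p = 0.061 with an estimated correlation). The DKK1 call was lost when libraries of adjacent number were averaged (adjusted p = 0.139), with voom (0.061), and without libraries 1 and 2 (0.107) or 5 and 6 (0.073) of each group. Its change was also under the minimum on the variance-stabilised scale (-0.68), without PP library 5 (-0.96) and without sorted library 2 (-0.96). The change of VIM was -0.77 without libraries 1 and 2 of each group. Other large falls were those of the cell cycle inhibitor CDKN1A, from 19.3 ± 13.1 to 0.501 ± 0.191, and the chemokine CXCL14, from 12.2 ± 4.74 to 0.680 ± 0.289. The cystatin CST1 fell from 28.1 ± 12.9 to 3.23 ± 2.39.

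The respiratory chain lists were higher in sorted PP at the preset correlation alone, and the glycolysis list was not called (median -0.01, adjusted p = 0.58). None of 23 nuclear respiratory chain genes passed the minimum change, and the list had a median of 0.23 (adjusted p = 3.3e-05; adjusted p = 0.19 with an estimated correlation). None of 13 mitochondrially encoded mRNAs passed it either, at a median of 0.44 (adjusted p = 0.030; adjusted p = 0.63 with an estimated correlation), beside the mitochondrial share of 16.7% given above. Several of the largest rises were in short non-coding RNAs. Among signal recognition particle RNA genes, Metazoa_SRP (ENSG00000278771) rose from 8.84 ± 3.78 to 75.0 ± 29.0, RN7SL2 from 5.85 ± 3.05 to 44.6 ± 24.5 and RN7SL5P from 1.75 ± 0.483 to 10.8 ± 3.86. The spliceosomal RNA gene U1 (ENSG00000278099) rose from 0.461 ± 0.302 to 8.80 ± 3.74. The mitochondrial transfer RNAs rose as well, MT-TT from 24.4 ± 10.6 to 156 ± 16.2 and MT-TH from 0.504 ± 0.622 to 5.84 ± 1.47. The microRNA gene MIR6087 fell from 151 ± 35.5 to 16.0 ± 6.47. Such genes are short, and the signal recognition particle and U1 genes have many near-identical copies, so their levels are uncertain. On the variance-stabilised scale the changes of MT-TH, U1 and RN7SL5P were 0.36, 0.66 and 0.75.

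**Figure D3:**
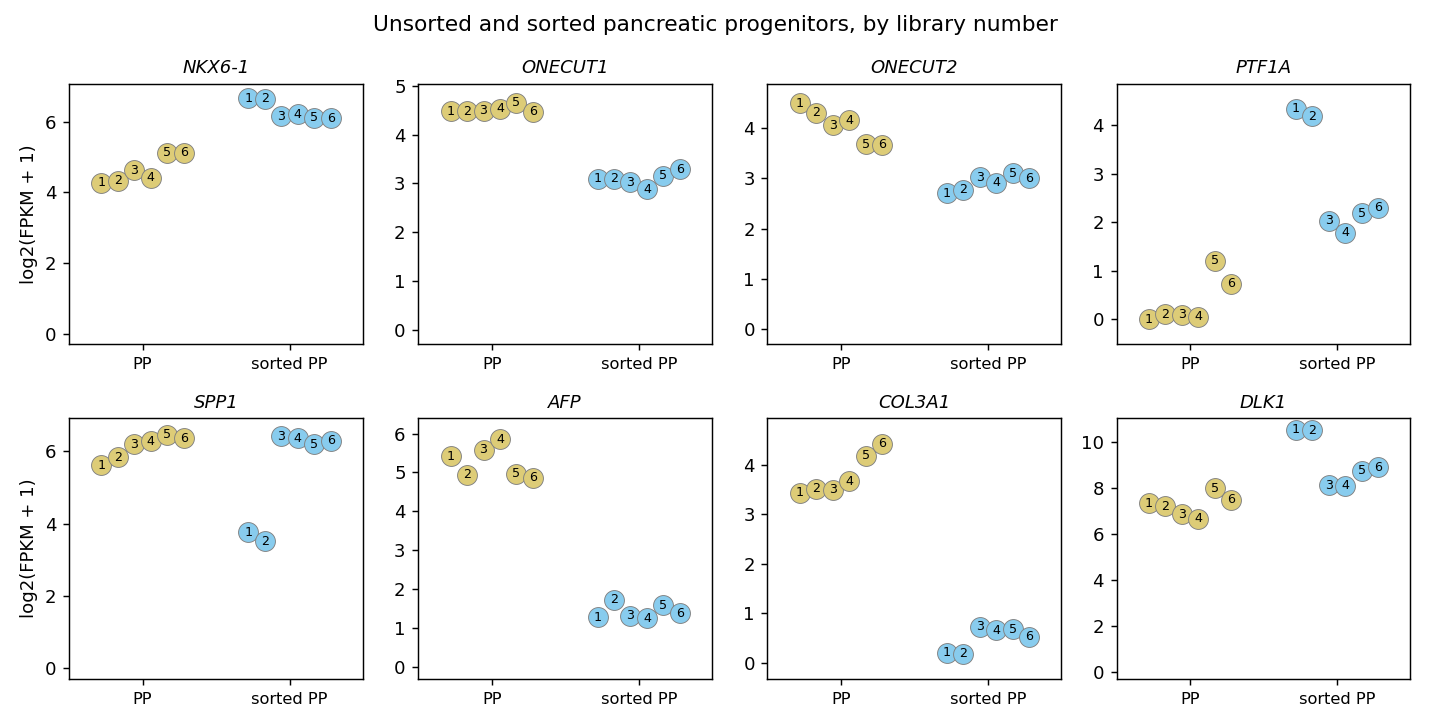
Expression of 8 genes in PP and sorted PP (x axis) as log2(FPKM + 1) (y axis); each point is 1 library and carries its number in the labels. All 6 sorted libraries lay below all 6 PP libraries for ONECUT1, ONECUT2, AFP and COL3A1, and sorted libraries 1 and 2 stood apart from the other 4 for PTF1A, SPP1 and DLK1.

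Between sorted PP and PP 364 genes changed, 129 higher and 235 lower in sorted PP, and of 12984 protein-coding genes 45 rose and 155 fell. Of the 17437 genes tested, 4778 had no overlap between the groups, against 0.216% by chance with all libraries exchangeable and 10% with averages of adjacent numbers. Of 29 lists, 8 were called, 3 higher and 5 lower, and the liver and mesenchyme lists held with an estimated correlation. Median, mean and test differed in sign for the ductal, Nodal and gut tube lists, none of which was called. Without libraries 1 and 2 of each group 268 genes changed, 107 higher and 161 lower. The manner of sorting, and whether sorted and unsorted cells came from the same cultures, is not given in the sources used here.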

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

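The tests of why libraries of adjacent number resemble each other and of the lower ONECUT1 in sorted PP were chosen after these results had been seen. Libraries 1 and 2, 3 and 4, or 5 and 6 of a group deviated together from the group mean, with a median correlation of 0.406. Similar depth was argued against, because pairs whose depths differ at least 1.5-fold (8 pairs) still correlated at a median of 0.412, against at most 0.0135 for other libraries of a group. A batch shared by equal numbers in every stage was argued against as the whole cause, because the highest mean correlation between neighbouring stages was 0.189, although 7 of 24 same-numbered libraries correlated above 0.1 and a batch shared by part of them stays open. Separate cultures with a pair of libraries each could give the consensus correlation of 0.645, but no label names cultures, so this stays open.

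ONECUT1 was lower in sorted PP than in PP, at 34.4% of its PP level. Scaling was argued against for the fall relative to other genes, because a library factor shifts all genes alike. The median change of all genes was 0.0038 beside -1.43 for ONECUT1, and 0.0089 beside -1.43 when libraries were scaled to total reads. The first of these medians lies near 0 because of the library factors in the deposited values, so it is no evidence by itself. Scaling to total reads moved the median by only 0.00516, so it tested little by itself. Both scalings are relative, so the amount of ONECUT1 RNA per cell stays open. RNA from cells outside the gate could account for it if these held about 28.5 FPKM of ONECUT1, taking the 31.1% ratio of NKX6-1 as the gated share. This predicts less ONECUT1 where NKX6-1 is higher, whereas over the 3 number pairs of PP ONECUT1 averaged 21.4, 21.8 and 22.7 beside NKX6-1 of 18.8, 22.1 and 33.8 (1.14-fold and 1.83-fold ranges over libraries), a direction against the explanation, which stays open because 3 pairs allow no exact p below 0.333. A lower ONECUT1 level within the gated cells was not tested apart from this.

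A search of 124 sets of 6 libraries found 8 in which 1 library stood apart by Dixon's ratio, and chance marks about 1 in 20 sets. TDGF1 was 2.58 in PE library 4 against at most 1.65 in the others (ratio 0.627). ONECUT1 was 24.3 in PP library 5 against 21.2 to 22.2 (ratio 0.671). Sorted library 1 was high for Metazoa_SRP, at 133 against 55.9 to 70.8 (ratio 0.728). It was also high for RN7SL2, at 94.3 against 30.3 to 38.4 (ratio 0.793), and for RN7SL5P, at 18.6 against 8.49 to 10.8 (ratio 0.697). MIR6087 was 85.2 in PP library 6 against 146 to 191 (ratio 0.665). PP library 6 also had the fewest reads of its group, 9.35 M against 16.5 to 19.9 M (ratio 0.679). Mitochondrially encoded genes took 9.38% of FPKM in PE library 2 against 10.7 to 11.5% (ratio 0.660).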

How the results depend on the processing

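Most results of named genes kept their call and direction under other settings, although counts and sizes moved. The naming rule took mainly called genes with the largest changes. Their selection therefore favoured this outcome, which says little about genes near the minimum change. For the named genes, 4484 of 4563 values under other settings were unchanged in call and direction, 52 were weaker, 25 stronger and 2 reversed. When single libraries were left out, 4176 of 4212 values were unchanged, 19 were weaker, 13 stronger and 4 reversed. The cause was not tested for any of these except where the construction of the alternative gives it.

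The minimum change set the number of genes called. Without it, 12617 genes were called in DE against ESC, 11696 in PE against DE, 7767 in PP against PE and 6453 in sorted PP against PP. A pseudocount of 0.1, which enlarges changes of low genes, gave 4329 in PE against DE, 1781 in PP against PE and 986 in sorted PP against PP. The variance-stabilised table, which shrinks them, gave 192 in sorted PP against PP, 46 higher and 146 lower.

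Further alternatives were added after the values had been seen. With voom on recovered reads, 5500, 4485, 1980 and 1138 genes were called in the 4 comparisons. Among protein-coding genes alone, 201 were called in sorted PP against PP. Averaging libraries of adjacent number gave 3619, 2834, 1007 and 319 genes, and without libraries 1 and 2 of each group 3553, 2936, 1046 and 268 were called. With averaging, the EMT list in DE against ESC, the Wnt list in PE against DE and the endocrine regulator list in PP against PE were no longer called, at adjusted p = 0.051 each.

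List calls depended on the correlation assumed between genes. With an estimated correlation, 3 lists were called in DE against ESC, 10 in PE against DE, 3 in PP against PE and 2 in sorted PP against PP. Without the low-value filter, 14 lists were called in sorted PP against PP.

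The ONECUT2 difference between PP and PE, which was not called, turned direction with the libraries used. It was 0.12 without PE library 3, 0.11 without PE library 4, 0.03 without PP library 5, 0.04 without PP library 6 and 0.33 without libraries 3 and 4 of each group, and it reached -0.20 without PE library 5 and, at the lowest, -0.24 without libraries 5 and 6 of each group. The ONECUT3 difference between sorted PP and PP, also not called, was -0.0151 without libraries 1 and 2 of each group.

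With the replicate number as a block, 3629, 2845, 1022 and 363 genes and 11, 16, 12 and 8 lists were called, and 8374 genes were stage-variable. The lists lost with the block were EMT in DE against ESC and Wnt targets in PE against DE, at adjusted p = 0.052 each. Pairing by number was not used, because correlations of same-numbered libraries between neighbouring stages ran from -0.088 to 0.184, with 7 of 24 above 0.1.

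Leaving out 1 library at a time gave 3553 to 3697 genes and 11 to 12 lists in DE against ESC, 2811 to 2881 genes and 17 to 19 lists in PE against DE, 1003 to 1042 genes and 11 to 12 lists in PP against PE, and 338 to 388 genes and 8 to 10 lists in sorted PP against PP. Stage-variable genes numbered 8309 to 8536. Depth of 8.64 to 22.6 M reads limits what can be said of genes with few reads, and tests for raw counts were not run because no table held them.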

Other observations

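The tests on RNAs without a poly-A tail were chosen after that pattern had been seen, with the histone and depth tests set before their own values were computed and the small nucleolar RNAs weighed afterwards, while the splits of libraries were set beforehand and those of number pairs afterwards. Single genes changed in lists that were not called. Endothelial genes gave adjusted p = 0.58, 0.12, 0.18 and 0.11 in the 4 comparisons, although VWF rose from 0.115 ± 0.0326 in ESC to 47.0 ± 14.8 in DE and fell to 0.221 ± 0.0655 in PE, while KDR fell from 29.7 ± 2.99 to 5.83 ± 2.11 and 0.461 ± 0.305. Neural ectoderm genes gave adjusted p = 0.97, 0.051, 0.57 and 0.42, and in DE against ESC median, mean and test differed in sign. OTX2, a factor of anterior endoderm as well as of the brain, rose to 218 ± 17.8 in DE and fell to 2.55 ± 0.605 in PE. Hedgehog pathway genes were called in PE against DE alone, where 4 of 10 rose (adjusted p = 0.024; adjusted p = 0.29 with an estimated correlation), with the ligand IHH going from 1.48 ± 0.541 to 15.4 ± 7.67 and then falling to 0.666 ± 0.178 in PP. SHH fell from 2.52 ± 0.777 in PP to 0.368 ± 0.154 in sorted PP, and the immediate early gene FOS rose from 6.97 ± 2.05 to 19.2 ± 4.12.

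No class of non-coding RNA was tested as a whole between sorted PP and PP. All 17 mitochondrial transfer RNAs tested lay above 0, with a median change of 1.05 and 7 called higher. Of 58 miscellaneous RNAs 4 were higher and 1 lower (median -0.11), and of 37 small nuclear RNAs 4 were higher and 3 lower (median -0.05). Of 197 small nucleolar RNAs, 20 were lower and 1 higher, and of 117 microRNA genes 12 were lower and 3 higher. Of 597 long intergenic RNAs 22 rose and 8 fell, and of 536 antisense RNAs 12 rose and 2 fell. Many of these genes are short or overlap others, so their levels are uncertain.

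Of the mitochondrial transfer, miscellaneous and small nuclear RNAs, classes that largely lack a poly-A tail, 15 genes were called higher in sorted PP, although only the first class had a median above 0. Different recovery of such RNA may contribute, since 13 of 15 replication-dependent histone genes lay above 0, with a median of 0.50 that exceeded all 10000 random lists. Of these histone genes, only 1 was called higher. The random lists were matched on expression alone, so they do not allow for histone genes moving together. Small nucleolar RNAs, which also lack a tail, had a median of -0.19, so the explanation stays open. Depth was argued against, because the deeper of libraries 1 and 2 differed from the shallower by 0.21 and of libraries 3 and 4 by 0.33 over these 15 genes, whose change had a median of 1.70. A higher share of dividing cells would raise histone RNA too and stays open, as the cell cycle list had a median of 0.14 (adjusted p = 0.080) and the inhibitor CDKN1A fell from 19.3 to 0.501; no other biological explanation was tested.

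Splits of the libraries into mixed groups asked whether mixed groups give as many calls, using 100 splits with the real one included. For genes, chance can be excluded if the libraries are taken as separate, as 1 split of 100, the real one, reached the observed count in each comparison. The counts were 3629 against at most 1872 in other splits for DE against ESC, 2844 against 1546 for PE against DE, 1022 against 517 for PP against PE, 364 against 141 for sorted PP against PP, and 8381 against 2568 for stage-variable genes. Libraries of adjacent number resembled each other, and with these averaged only 10 splits of 3 against 3 exist, too few for a share under 0.05. In these splits 3619, 2834, 1007 and 319 genes were called in the real grouping, against at most 0, 1, 0 and 1 in the others. For lists in DE against ESC the real 12 exceeded the highest other count of 11, so 1 split reached it, again with libraries taken as separate. By these splits chance cannot be excluded for the number of lists called elsewhere. In PE against DE 11 splits reached the real 17 (highest other 18), and in PP against PE 11 reached the 12 (highest other 14). In sorted PP against PP 48 reached the 8 (highest other 14). Mixed groups need not hold equal parts of both stages, so a split can keep part of the real difference and call the same lists. Similar counts therefore do not show that the list calls arose by chance.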
